A study of Mus musculus with 6 samples.

How the data were processed

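Total RNA was extracted from mouse lung with a column kit and made into standard Illumina libraries, per the labels' protocols. The authors deposited 1 table of raw gene counts, with whole numbers for 24061 gene identifiers in 6 libraries and no normalization. The tools named in the submitters' processing notes are bcl2fastq and CASAVA 1.8, TopHat and DESeq, with the mouse genome build mm10. Which tool counted the reads, its strand setting, the gene annotation and the other versions were not given in the sources used here. Column names were matched to samples by the description label of each sample. Without a stated strand setting, overlapping and antisense genes cannot be separated. Of the 24061 rows, 4514 held 0 in every library, and 96 rows had the same 6 counts as another row (total over 100 counts), as near-identical gene copies do.

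Gene identifiers were paired with symbols and coordinates through a table of RefSeq genes on GRCm38.p6, the same build as mm10. It named 23976 identifiers and left 85 without a symbol. The unnamed identifiers took 2.13, 2.8 and 1.73% of the counts in control replicates 1 to 3 and 3.03, 3.8 and 3.45% in TGFalpha replicates 1 to 3. They were kept in library totals and tests and are not named. Totals ran from 21479006 to 24914322 counts per library. No duplicate libraries were found, since the chi-square over its degrees of freedom between libraries of a group was 46.6 or more.

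Groups were taken from the titles and genotype labels, with 3 libraries each. The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the expression filter of edgeR by group, a model of group only and Benjamini-Hochberg adjustment. The threshold was an adjusted p of 0.05. Standard errors of log2 fold changes were derived from the fitted coefficient and the F statistic. CPM values use the scaled library sizes, except the skeletal muscle sums and the Acta1 levels, which use unscaled library totals. Means are given with the SD over the 3 libraries of a group. The common biological coefficient of variation was 0.295.

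A set of 39 gene lists with 898 members was fixed before the data were examined, covering pathways, lung cell types, other tissues, RNA quality and dissection stress. Of the members, 886 were matched. The sex check list was kept out of the family, and all 6 libraries had the female pattern of Xist with 0 to 5 counts of each Y-linked gene. The other 38 lists, each with at least 5 tested members, were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), at a preset correlation of 0.01 and 2-sided, with Benjamini-Hochberg adjustment over the lists. Counts of members are given adjusted over all genes and adjusted over the list alone. The same lists were also tested with an estimated correlation and with fry. With an estimated correlation camera also uses the few residual degrees of freedom, so a high adjusted p there does not reflect correlation alone.

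The genes named were set by a rule before the data were examined. It takes Tgfa and Egfr. It takes the 8 largest rises and the 8 largest falls among genes past the threshold with a mean of at least 1 CPM and no overlap between groups, leaving out Xist, Y-linked genes, provisional symbols, pseudogenes and small RNAs. It takes from each called list the 3 members with the smallest adjusted p and the largest called change against the list's direction, and from each other list the 1 member with the smallest adjusted p. The rule gave 97 genes, of which 79 were called. Ager, Aqp5, Pdpn, Rtkn2, Scgb1a1, Col1a1, Col1a2, Col3a1, Gata2, Mcpt2 and Tpsab1, and the genes that open the other observations, were chosen after their values were seen. For genes with no control counts a floor of 3 counts over the group was used, and for Twist1 a 95% counting interval.

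The edgeR step was tested on simulated counts with the means and library sizes of these samples and 200 changed genes. For TGFalpha against control over 15759 genes it recovered 16% of 2-fold and 84.7% of 4-fold changes, with 8 false calls (7.5% of calls). DESeq2 recovered 46% and 90% over 16074 genes, with 20% of its calls false. The camera step called the 1 shifted list of 38 and no other. The simulated genes were drawn independently of each other, so this does not test the preset correlation. In the real data the estimated correlation was 0.552 for the endothelial list and 0.977 for the skeletal muscle list.

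The alternatives planned were DESeq2's size factors, library totals as the only scaling, no filter, a stricter filter (1 CPM in 3 libraries), DESeq2 1.42.0, limma-voom, a replicate block, leaving out the 20 most abundant genes, a robust fit, each library left out in turn, an adjusted p of 0.01 and a test against a 1.5-fold change. Added after seeing the data were the removal of control replicate 1 and TGFalpha replicate 1 together, and 1 surrogate variable from sva 3.50.0. Transcript length and GC content for a trend check came from GENCODE M21 transcripts, which covered 94.5% of the tested genes. Figures were drawn with matplotlib 3.10.9.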

Results

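Messenger RNA levels were measured by bulk RNA sequencing of whole mouse lung in 2 groups of 3 samples. The control group carried CCSP alone (genotype CCSP/-), and the other group carried CCSP together with TGFalpha (CCSP/TGFalpha). Both groups had received doxycycline for 3 weeks. CCSP is the club cell secretory protein, whose promoter is used in mice to direct a transgene to lung epithelium. TGFalpha is a growth factor that binds the epidermal growth factor receptor (EGFR). The comparison asks which lung transcripts differed between mice with and without the TGFalpha transgene while all were given doxycycline. Gene counts per library summed to 24837861, 22311431 and 21479006 in control replicates 1 to 3 and to 23622798, 24914322 and 23317747 in TGFalpha replicates 1 to 3. Nothing in the labels says whether the replicates came from separate animals, so the p-values measure only the spread between these samples.

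The lungs of CCSP/TGFalpha mice held far more transcript of extracellular matrix genes than the control lungs, and less transcript of many endothelial, alveolar type 1 and ciliated cell genes. Of 31 tested genes of fibrillar collagen and matrix, 23 rose. Tnc, which encodes the matrix glycoprotein tenascin C, went from 23.6 ± 6.37 to 983 ± 187 CPM (counts scaled to a common library size; mean ± SD, n = 3 per group). Of 30 tested endothelial genes, 10 fell, among them Tek, the angiopoietin receptor, from 395 ± 109 to 123 ± 55.4 CPM. Across the 16089 genes tested with edgeR, 1340 changed at a Benjamini-Hochberg adjusted p under 0.05, of which 810 (60.4%) rose and 530 (39.6%) fell. At least 2-fold changes were found for 917 genes, 572 up and 345 down. The 2 groups did not overlap in CPM for 5349 genes (33.2%), where the average over all splits of the 6 libraries 3 against 3 is 10% for genes without ties. The share in the other splits was not counted. Genes that move together can carry 1 split far from that average. The number of changed genes depended on single libraries: it was 307 without control replicate 2, 238 without control replicate 3, 411 without TGFalpha replicate 1 and 564 without TGFalpha replicate 2. Only 43 and 34 genes fell without control replicates 2 and 3.

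**Figure D1:**
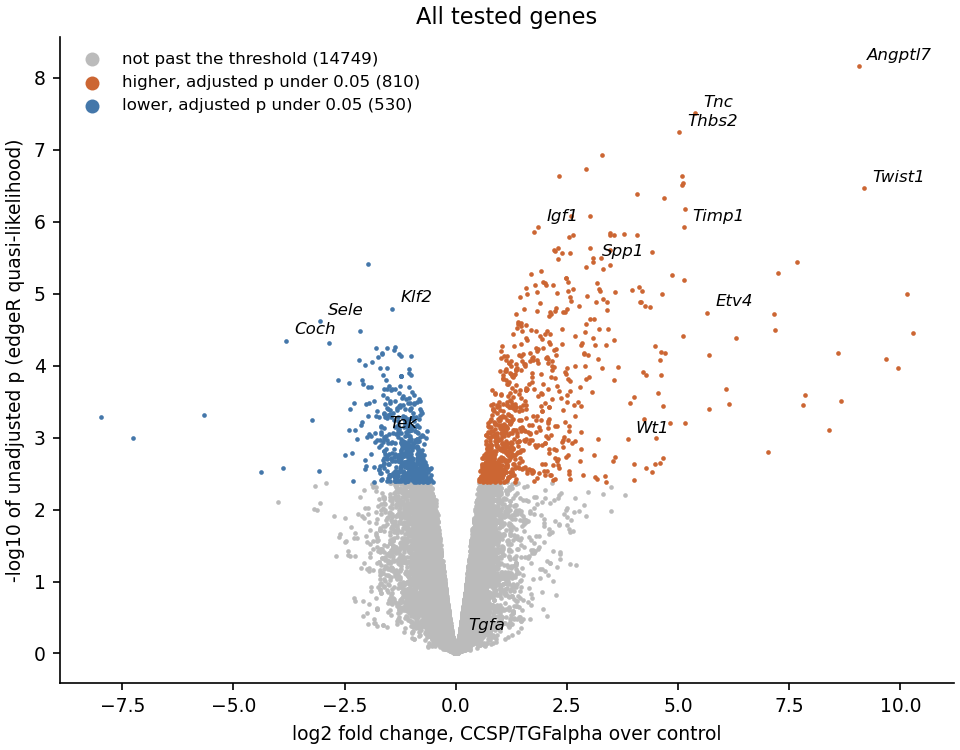
Each point is 1 of the 16089 tested genes, with the log2 fold change of CCSP/TGFalpha over control on the x axis and the unadjusted edgeR p on a negative log10 scale on the y axis. The 810 genes that rose (orange) reach larger changes than the 530 that fell (blue), Angptl7 has the smallest p, and Tgfa lies near 0; fitted changes of genes with no control counts depend on the prior count.

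The gene named in the genotype did not separate the groups. Tgfa (gene ID 21802; GRCm38, chromosome 6, 86195038 to 86275744) was at 25.8 ± 2.94 CPM in controls and 27.5 ± 2.09 CPM in CCSP/TGFalpha lungs, a log2 fold change of 0.09 ± 0.16 (SE; edgeR adjusted p = 0.739). Its 95% interval ran from -0.21 to 0.4. The mouse gene row would hold reads of a transgene only as far as the transgene sequence matches the mouse gene, and the species and extent of the transgene were not given in the sources used here. Egfr (gene ID 13649; chromosome 11, 16752203 to 16913907), the receptor of TGFalpha, rose from 29.8 ± 4.51 to 49.6 ± 6.88 CPM (log2 fold change 0.74 ± 0.17, edgeR adjusted p = 0.0414). Its call was lost when any 1 library was left out, with adjusted p between 0.058 and 0.14. Among 9 tested EGFR ligands and receptors, Egfr and the ligand Ereg rose (2 adjusted over the list alone). Ereg went from 0.422 ± 0.317 to 10.7 ± 5.59 CPM, and the median log2 fold change of the list was 0.09.

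Feedback genes of the ERK pathway, which signals downstream of EGFR, were among those that rose. Of 23 tested genes of ERK feedback and immediate early response, 6 rose and 1 fell (6 and 1 adjusted over the list alone). The transcription factor gene Etv4 went from 0.224 ± 0.201 to 11.8 ± 4.85 CPM (log2 fold change 5.65 ± 0.65). The ERK phosphatase gene Dusp4 rose from 10.9 ± 2.79 to 48.7 ± 19.6 CPM, and the inhibitor gene Spred1 from 152 ± 14.1 to 317 ± 42.6 CPM. Fos, an immediate early gene, went the other way, with a log2 fold change of -0.75 ± 0.13 (adjusted p = 0.0179). The list shifted up by camera (adjusted p = 0.034), with an adjusted p = 0.71 with an estimated correlation and 0.068 by fry. Its call was lost without TGFalpha replicate 2 (adjusted p = 0.062). Only 2 members rose without control replicate 2 or control replicate 3, and 3 without TGFalpha replicate 1 or TGFalpha replicate 2. The calls of Spred1 and Fos were among those lost without control replicate 2 (adjusted p = 0.051 and 0.062) and control replicate 3 (0.058 and 0.086), that of Dusp4 without control replicate 2 (0.054), and that of Fos also without TGFalpha replicate 2 (0.06).

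**Figure D2:**
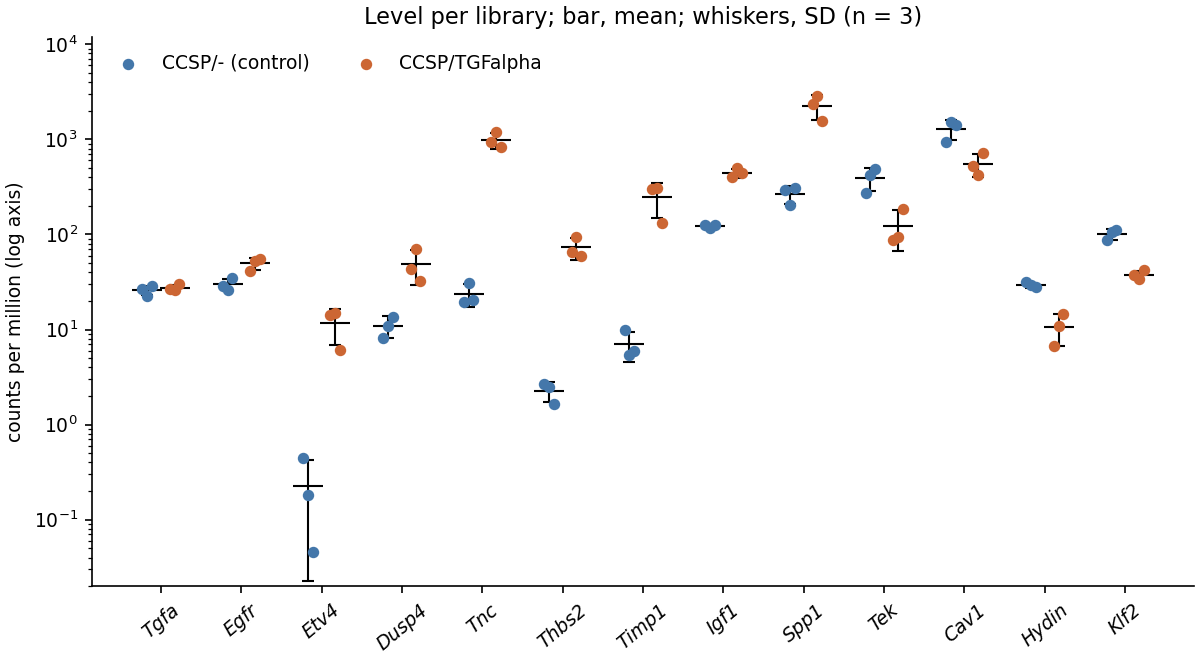
CPM (log axis) of 13 genes in each of the 3 control (blue) and 3 CCSP/TGFalpha (orange) libraries, with the mean as a bar and the SD as whiskers. Tgfa levels overlap between the groups, whereas for the other genes shown every CCSP/TGFalpha library lies on one side of every control library.

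Matrix genes gave the largest shift of any list. The median log2 fold change of the 31 fibrillar collagen and matrix genes was 1.82, and the 23 genes that rose were the same number when adjusted over the list alone. The matrix glycoprotein genes Tnc (log2 fold change 5.38 ± 0.28, edgeR adjusted p = 0.000246), Thbs2 (5.01 ± 0.28) and Vcan (4.69 ± 0.34) led the list. Tnc has gene ID 21923 and lies on chromosome 4 from 63959785 to 64047015. The genes of the fibrillar collagen chains Col1a1, Col1a2 and Col3a1 were also among those that rose. The list shifted up by camera (adjusted p = 1.6e-15), and the adjusted p = 0.66 with an estimated correlation. By fry, which tests whether a list's genes move one way on balance, the adjusted p was 0.011. Without control replicate 3, 15 matrix genes rose, and 21 rose with control replicate 1 and TGFalpha replicate 1 both left out.

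Part of the genes for enzymes that process collagen and matrix rose. Of 18 tested genes for collagen cross-linking and maturation, 9 rose (13 up and 2 down adjusted over the list alone), with a median log2 fold change of 0.90 and negative values for 3. A cross-linking gene fell without control replicate 1 or TGFalpha replicate 3 (1 in each). Those that rose included the lysyl oxidase family genes Loxl1, from 26.3 ± 4.24 to 108 ± 22 CPM, and Loxl2, from 45.2 ± 9.58 to 271 ± 86.7 CPM. Bmp1, which encodes a procollagen C-proteinase, rose from 39.2 ± 3.88 to 205 ± 50.3 CPM. Camera gave an adjusted p of 2e-05, against an adjusted p = 0.66 with an estimated correlation and 0.011 by fry. Among 25 matrix proteases and inhibitors, 10 rose (11 adjusted over the list alone), with a median of 0.32 and negative values for 9. Timp1, an inhibitor of metalloproteinases, rose from 7.06 ± 2.46 to 248 ± 100.2 CPM, Adamts12 from 1.16 ± 0.246 to 39.7 ± 16 CPM and the gelatinase gene Mmp2 from 106 ± 9.82 to 346 ± 51.1 CPM. For that list the camera adjusted p was 0.0031, with an adjusted p = 0.71 with an estimated correlation and 0.033 by fry. The count of proteases and inhibitors that rose was 5 without control replicate 3.

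Genes of the TGF-beta response, a pathway separate from TGFalpha and EGFR, moved both ways. Of 21 tested, 6 rose and 2 fell (8 up and 4 down adjusted over the list alone). Tgfb3 rose from 15.8 ± 1.84 to 77.8 ± 17.2 CPM, Ltbp2 from 28.1 ± 3.72 to 81.6 ± 12.2 CPM and Tgfbi from 77.5 ± 1.98 to 172 ± 27 CPM. Ccn1 fell, with a log2 fold change of -0.74 ± 0.18 (adjusted p = 0.0442). By camera the list had an adjusted p of 0.047, and the adjusted p = 0.73 with an estimated correlation. The call was lost without control replicate 1, control replicate 3 or TGFalpha replicate 2 (adjusted p = 0.07, 0.053 and 0.16), and with 1 surrogate variable (0.077). Without control replicate 3 only 3 members rose. The falls numbered 1 without TGFalpha replicate 3 and none by edgeR without control replicate 2, control replicate 3, TGFalpha replicate 1 or TGFalpha replicate 2, where 3, 2, 3 and 3 were lower at an unadjusted p under 0.05. The Ccn1 call was lost without any 1 library other than control replicate 1 (adjusted p between 0.075 and 0.17).

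Fibroblast and contractile genes changed less uniformly. Of 22 tested fibroblast genes, 5 rose (6 adjusted over the list alone), with a median log2 fold change of 0.20 and a camera adjusted p of 0.081. The list was called without control replicate 2 or control replicate 3 (adjusted p = 0.03 and 0.015), while 2 of its genes rose without control replicate 2, control replicate 3, TGFalpha replicate 1 or TGFalpha replicate 2, and 3 without TGFalpha replicate 3. Without control replicate 1, 1 fibroblast gene fell. The growth factor gene Igf1 rose from 123 ± 5.05 to 444 ± 47.5 CPM. In the myofibroblast and smooth muscle list 2 of 14 genes rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.36). Of these genes 1 rose without control replicate 1, control replicate 2, TGFalpha replicate 1 or TGFalpha replicate 2, and none by edgeR without control replicate 3, where 5 were higher at an unadjusted p under 0.05. None fell by edgeR without control replicate 2, control replicate 3, TGFalpha replicate 1 or TGFalpha replicate 2, where 1 was lower at an unadjusted p under 0.05 in each. Tagln rose from 61.9 ± 18.2 to 248 ± 100.6 CPM, and its call was lost without control replicate 2 or control replicate 3 (adjusted p = 0.069 and 0.064). In the mesothelial list 2 of 12 genes rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.53). No mesothelial gene rose by edgeR without control replicate 2, TGFalpha replicate 1 or TGFalpha replicate 2, where 3 were higher at an unadjusted p under 0.05 in each, and 1 fell only without TGFalpha replicate 1 among the fits with 1 library left out. In the other 5 of these, 1, 1, 4, 1 and 2 were lower at an unadjusted p under 0.05. Wt1, a transcription factor gene of mesothelium, rose from 8.23 ± 6.54 to 120 ± 30.9 CPM, with control libraries at 11.2, 12.7 and 0.731 CPM. The Wt1 call was lost without control replicate 2, TGFalpha replicate 1 or TGFalpha replicate 2 (adjusted p = 0.088, 0.081 and 0.064), and in the robust edgeR fit (0.091). No pericyte gene of 10 passed with the main edgeR fit or limma-voom, 1 fell by DESeq2, and 1 had a lower level at an unadjusted p under 0.05. Notch3 had the smallest adjusted p there (0.111), and it passed as a fall in the edgeR fit with 1 surrogate variable (0.007). In the basement membrane list 3 of 22 genes rose, among them Lamb1, and 1 fell (3 and 4 adjusted over the list alone). The Lamb1 call was lost without control replicate 2, control replicate 3 or TGFalpha replicate 2 (adjusted p = 0.057, 0.1 and 0.064). Of the basement membrane genes 1 rose without control replicate 1, TGFalpha replicate 1 or TGFalpha replicate 3, and none by edgeR without control replicate 2, control replicate 3 or TGFalpha replicate 2, where 4, 3 and 3 were higher at an unadjusted p under 0.05. Without TGFalpha replicate 3, 4 fell, and none did by edgeR without control replicate 1, control replicate 2, control replicate 3 or TGFalpha replicate 2, where 6, 5, 4 and 4 were lower at an unadjusted p under 0.05. The median of that list was 0.06, its mean was -0.02 and camera placed it down (adjusted p = 0.92).

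Endothelial and alveolar type 1 transcripts were lower in CCSP/TGFalpha lungs. In the endothelial list 10 of 30 genes fell, 25 did when adjusted over the list alone, and the median log2 fold change was -1.08. Tspan7 fell from 482 ± 119 to 178 ± 74.7 CPM and Lyve1, a lymphatic endothelial marker, from 88.2 ± 17.1 to 38.7 ± 8.83 CPM. Camera gave an adjusted p of 4.8e-10, and the adjusted p = 0.71 with an estimated correlation and 0.087 by fry. In 1 other split of the 6 libraries the unadjusted camera p of the endothelial list was lower (1.8e-14 against 3.8e-11). Alveolar type 1 cells are the flat cells of gas exchange. Of their 18 genes 7 fell (1 up and 13 down adjusted over the list alone), with a median of -0.85 and negative values for 17. The markers Ager, Aqp5, Pdpn and Rtkn2 were among the 11 genes that did not pass when adjusted over all genes. The list's mean log2 levels relative to the control mean were -0.28, 0.13 and 0.15 in control replicates 1 to 3. They were -0.83, -1.06 and -0.32 in TGFalpha replicates 1 to 3, so TGFalpha replicate 3 lay close to control replicate 1. Cav1 fell from 1291 ± 308 to 554 ± 149.6 CPM, Clic5 from 1099 ± 229 to 509.6 ± 154.5 CPM, and Vegfa, a growth factor for endothelium, from 785 ± 204 to 341 ± 109 CPM. For this list camera gave an adjusted p of 2.2e-05, and the adjusted p = 0.71 with an estimated correlation and 0.12 by fry. Its unadjusted camera p was also lower in 1 other split (3.8e-09 against 4.1e-06). The counts of falling endothelial genes varied with the libraries. They were 19 without control replicate 1, 2 without TGFalpha replicate 1, and 0 without control replicate 2, control replicate 3 or TGFalpha replicate 2, where 20, 21 and 21 were lower at an unadjusted p under 0.05. No alveolar type 1 gene fell without control replicate 2, control replicate 3, TGFalpha replicate 1 or TGFalpha replicate 2 by edgeR, where 11, 10, 10 and 9 were lower at an unadjusted p under 0.05, and 1 rose without TGFalpha replicate 2. The calls of Tek, Tspan7, Cav1, Clic5 and Vegfa were lost without control replicate 2, control replicate 3, TGFalpha replicate 1 or TGFalpha replicate 2 (adjusted p between 0.075 and 0.15), and that of Lyve1 without control replicate 2, control replicate 3 or TGFalpha replicate 2 (0.067, 0.09 and 0.051). With 1 library left out the list medians lay between -1.40 and -0.91 for endothelium and between -1.11 and -0.70 for alveolar type 1.

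Airway genes were divided. Of 27 tested ciliated cell genes, 9 fell (19 adjusted over the list alone), with a median log2 fold change of -0.84 and negative values for all 27. Ak7 fell from 28.5 ± 1.07 to 14.2 ± 1.43 CPM, the dynein gene Dnah11 from 24.7 ± 2.62 to 11.9 ± 1.33 CPM and Hydin from 29.4 ± 1.75 to 10.7 ± 3.92 CPM. Camera gave an adjusted p of 1.2e-11, with an adjusted p = 0.6 with an estimated correlation and 0.011 by fry. The number of ciliated genes that fell was 1 without control replicate 2, 2 without control replicate 3, 4 without TGFalpha replicate 2, and 5 without each of the other libraries. Without control replicate 2 the calls of Hydin and Dnah11 were lost (adjusted p = 0.074 and 0.062), and that of Hydin also without control replicate 3 or TGFalpha replicate 2 (0.078 and 0.057). Of 20 club cell genes, 4 fell and 1 rose (6 and 1 adjusted over the list alone). The falls numbered 1 without control replicate 1 or control replicate 2, and none by edgeR without control replicate 3, TGFalpha replicate 1 or TGFalpha replicate 2, where 6 were lower at an unadjusted p under 0.05 in each. Gsta3 fell from 69.2 ± 13.2 to 33 ± 8.75 CPM and Gabrp from 112 ± 3.55 to 61.5 ± 15.6 CPM, while Bpifa1, an airway secretory gene, rose from 50.5 ± 44.3 to 436 ± 275 CPM. Scgb1a1, the gene of CCSP, was also among the falls (log2 fold change -1.32 ± 0.34, edgeR adjusted p = 0.0491). It passed in 1 of the 6 edgeR fits with 1 library left out and was lower in all 6. The club cell list shifted down by camera (adjusted p = 0.038), with an adjusted p = 0.73 with an estimated correlation. That call was lost without control replicate 2 or TGFalpha replicate 2 (adjusted p = 0.057 and 0.24), and with 1 surrogate variable (0.053). The calls of Gsta3, Gabrp and Bpifa1 were lost without control replicate 2, control replicate 3, TGFalpha replicate 1 or TGFalpha replicate 2 (adjusted p between 0.067 and 0.15), that of Gabrp also without control replicate 1 (0.056), and that of Bpifa1 also in the robust fit (0.094). In the mucous cell list 1 of 19 genes rose, Creb3l1, and 1 fell (1 and 2 adjusted over the list alone). The Creb3l1 call was lost without control replicate 3 (adjusted p = 0.073), and with 1 library left out a mucous gene fell only without TGFalpha replicate 2, while 2, 4, 4, 3 and 2 were lower at an unadjusted p under 0.05 in the others. The median of that list was 0.08, its mean was -0.12 and camera placed it down (adjusted p = 0.47).

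Surfactant-producing alveolar type 2 cells gave no called gene. With the main edgeR fit and limma-voom none of 23 tested genes passed. With DESeq2 2 rose and 1 fell, and at an unadjusted p under 0.05 the edgeR counts were 2 and 1. The list had a median log2 fold change of 0.11, a mean of -0.03 and a camera adjusted p of 0.98 in the downward direction. Napsa, which had the smallest adjusted p (0.0855), was at 172 ± 28.8 and 249.9 ± 23.1 CPM in control and CCSP/TGFalpha lungs. It passed in the edgeR fit with 1 surrogate variable (adjusted p = 0.046). Of 25 basal and transitional epithelial genes, 3 rose and 2 fell (5 and 5 adjusted over the list alone). With 1 library left out 1 to 4 rose, with 1 without control replicate 2 or control replicate 3. The falls numbered 1 without control replicate 1 or TGFalpha replicate 1 and none by edgeR without control replicate 2, control replicate 3 or TGFalpha replicate 2, where 4, 6 and 7 were lower at an unadjusted p under 0.05. Sox9, a transcription factor gene of distal lung progenitors, went from 0.733 ± 0.201 to 15.8 ± 6.69 CPM. That list had a median of -0.27, a mean of 0.22 and a camera adjusted p of 0.97 in the downward direction.

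**Figure D3:**
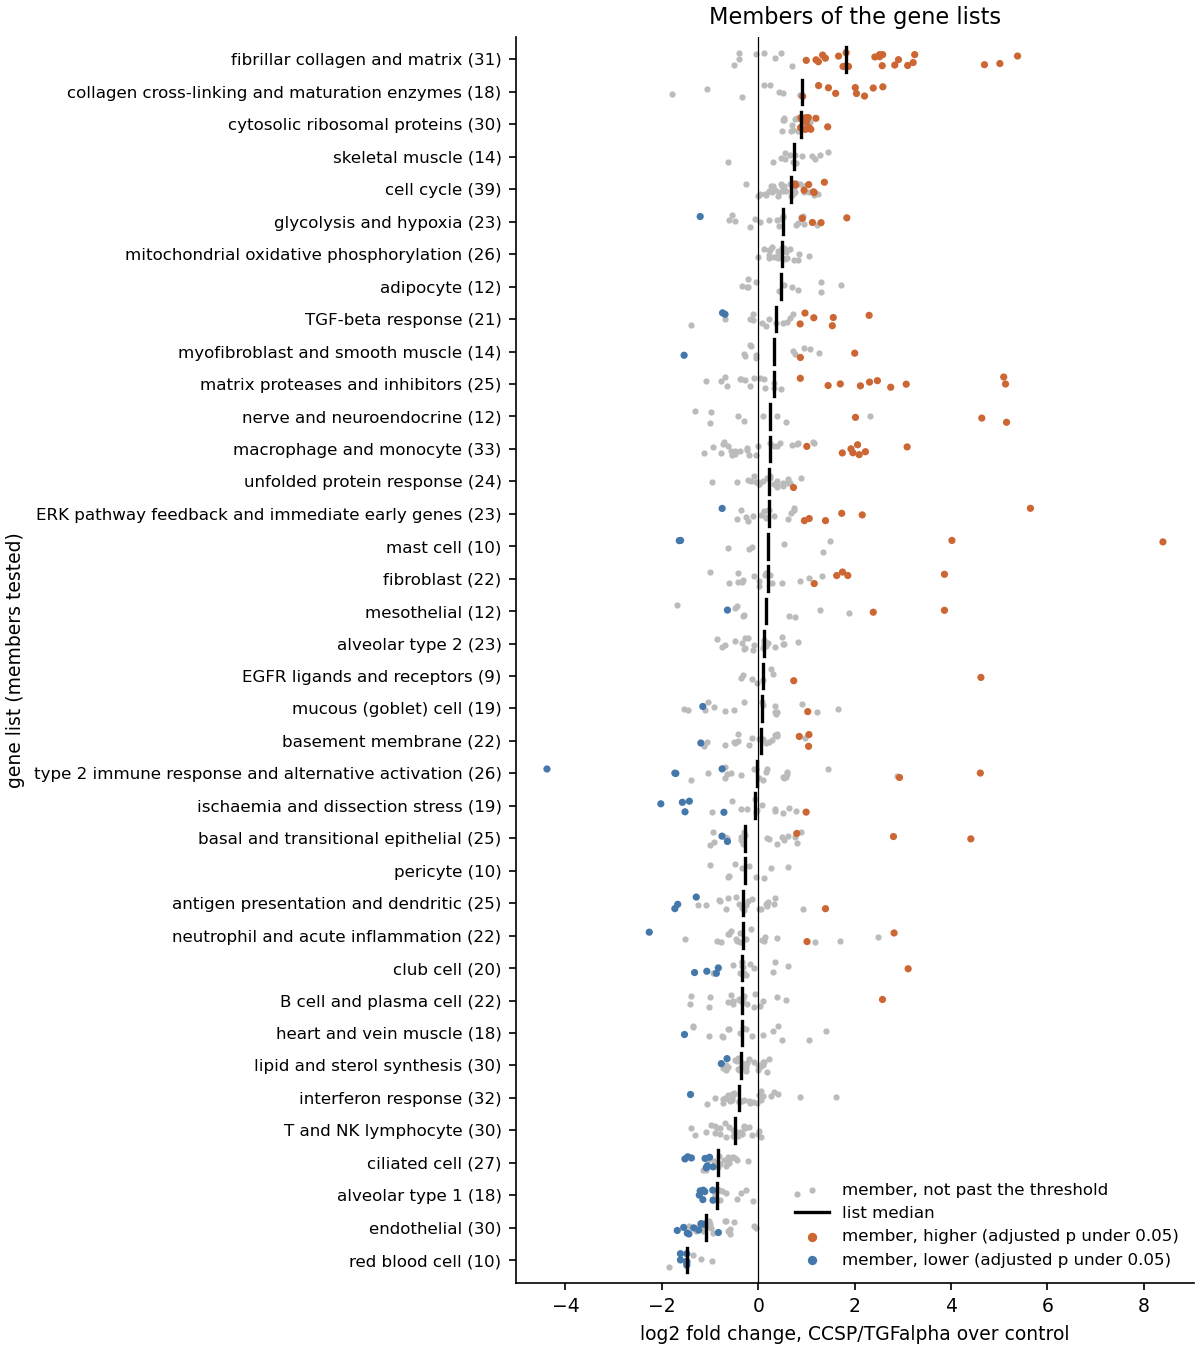
Log2 fold change (CCSP/TGFalpha over control, x axis) of every tested member of the 38 gene lists (y axis, members tested in brackets), with list medians as black bars and members past an edgeR adjusted p of 0.05 in colour. The fibrillar collagen and matrix list has the highest median, 1.82, and the red blood cell list the lowest, -1.48.

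Proliferation genes were higher as a group. Of 39 cell cycle genes, 7 rose (12 adjusted over the list alone), with a median log2 fold change of 0.69. The mitotic kinase gene Cdk1 rose from 11.1 ± 3.42 to 28.8 ± 7.47 CPM, the cyclin gene Ccnb1 from 9.18 ± 1.66 to 20.6 ± 2.73 CPM and Kif20a from 15.1 ± 0.987 to 25.9 ± 0.708 CPM. Camera gave an adjusted p of 1.8e-08, and the adjusted p = 0.71 with an estimated correlation and 0.079 by fry. The number that rose was 3 without control replicate 1 and 4 without TGFalpha replicate 2 or TGFalpha replicate 3. No member passed with edgeR without control replicate 2, control replicate 3 or TGFalpha replicate 1, where 26, 12 and 14 were higher at an unadjusted p under 0.05. In these 3 fits the adjusted p of Cdk1, Ccnb1 and Kif20a lay between 0.057 and 0.12, and Cdk1 also missed the threshold without TGFalpha replicate 2 (0.06) and Kif20a without control replicate 1 (0.055).

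Ribosomal protein genes, a list entered as a measure of RNA quality, were also higher as a group. Of 30 genes of cytosolic ribosomal proteins, 12 rose (24 adjusted over the list alone), with a median log2 fold change of 0.89 and a camera adjusted p of 1e-09. The adjusted p = 0.71 with an estimated correlation and 0.12 by fry. Rplp0 rose from 389 ± 53.4 to 890.5 ± 316 CPM, Rps2 from 297 ± 26.3 to 631 ± 204 CPM and Rpl23 from 157 ± 14.1 to 313 ± 90.3 CPM. TGFalpha replicate 1 was the highest library for each of these genes. Transcripts of the ribosomal list were short, with a median length of 1188 bases against 3313 for all tested genes. After a trend with transcript length and GC content was removed, the list median was 0.7. Whether RNA quality differed between the groups was not tested. No ribosomal protein gene passed with edgeR without control replicate 2, control replicate 3 or TGFalpha replicate 1, where 20, 22 and 20 were higher at an unadjusted p under 0.05, while 3 rose without control replicate 1 and 6 without TGFalpha replicate 2. The calls of Rps2 and Rpl23 were also lost without control replicate 1 (adjusted p = 0.053) and TGFalpha replicate 2 (0.054), respectively. In the glycolysis and hypoxia list 4 of 23 genes rose and 1 fell (10 and 3 adjusted over the list alone). The glycolytic genes Tpi1 and Pkm rose, with log2 fold changes of 1.30 ± 0.3 and 0.92 ± 0.21, and Vegfa was the gene that fell. The list shifted up by camera (adjusted p = 0.045), with an adjusted p = 0.77 with an estimated correlation, and the call was lost without control replicate 3, TGFalpha replicate 1 or TGFalpha replicate 2 (adjusted p = 0.1, 0.083 and 0.14). None of its genes rose by edgeR without control replicate 2, control replicate 3, TGFalpha replicate 1 or TGFalpha replicate 2, where 10, 7, 9 and 7 were higher at an unadjusted p under 0.05, while 1 rose without control replicate 1 and 7 without TGFalpha replicate 3.

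Oxidative phosphorylation genes, also entered as a measure of RNA quality, shifted up by camera (adjusted p = 0.0031, and adjusted p = 0.77 with an estimated correlation). None of 26 passed by itself with the main edgeR fit or limma-voom. At an unadjusted p under 0.05 there were 4 higher genes, and DESeq2 called 4 up. The lowest adjusted p belonged to Ndufb5 (0.069), at 141 ± 16.5 and 253 ± 88.5 CPM. In the edgeR fit with 1 surrogate variable Ndufb5, Ndufa4 and Ndufv2 passed (adjusted p = 0.018, 0.047 and 0.029). The list's call was lost without TGFalpha replicate 1 (adjusted p = 0.11), where its median went from 0.49 to 0.16. Its mean log2 level relative to the control mean was highest in the libraries with high skeletal muscle transcripts among their group, at 0.97 in TGFalpha replicate 1 against 0.24 and 0.10 in TGFalpha replicates 2 and 3, and at 0.24 in control replicate 1 against -0.17 and -0.07 in control replicates 2 and 3. In 6 of the other splits of the 6 libraries the oxidative phosphorylation list had a lower camera p than in the true grouping. Among 30 genes of lipid and sterol synthesis, Sqle and Insig1 fell, with log2 fold changes of -0.77 ± 0.17 and -0.65 ± 0.15 (2 adjusted over the list alone). The Sqle call was lost without any 1 library (adjusted p between 0.061 and 0.11). That of Insig1 was lost without any 1 other than TGFalpha replicate 3 (0.086 to 0.16), and with library totals as the only scaling (0.05). The median was -0.35 and the camera adjusted p was 0.0015, against an adjusted p = 0.71 with an estimated correlation. The lipid and sterol call was lost with control replicate 1 and TGFalpha replicate 1 both left out (adjusted p = 0.066). Of 24 genes of the unfolded protein response, Pdia4 rose (log2 fold change 0.72 ± 0.17). Without control replicate 1, 3 genes of that list rose. Pdia4 missed the threshold when adjusted over the list alone, and without any 1 library other than control replicate 1 (adjusted p between 0.05 and 0.17). By camera the unfolded protein response list had an adjusted p of 0.047, the adjusted p = 0.78 with an estimated correlation, and the call was lost without control replicate 2, control replicate 3, TGFalpha replicate 1 or TGFalpha replicate 2 (adjusted p = 0.084, 0.21, 0.063 and 0.25), with the stricter filter (0.05) and with 1 surrogate variable (0.053).

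Immune cell genes went in different directions. Of 33 macrophage and monocyte genes, 8 rose (9 adjusted over the list alone), with a median log2 fold change of 0.24 and a camera adjusted p of 0.05, which did not pass. It passed without control replicate 1, TGFalpha replicate 1 or TGFalpha replicate 3 (0.0099, 0.024 and 0.0023) and with the size factors of DESeq2 (0.047), and 4 of its genes rose without control replicate 2 or control replicate 3. Without TGFalpha replicate 2 the macrophage median turned to -0.03, with 8 genes lower at an unadjusted p under 0.05, against 1 with all libraries. Spp1, the gene of osteopontin, rose from 267 ± 56.1 to 2269 ± 653 CPM. T and NK lymphocyte genes shifted down by camera (median -0.48, adjusted p = 7.4e-05; adjusted p = 0.71 with an estimated correlation). None of the 30 passed by itself with the main edgeR fit or limma-voom, 4 fell by DESeq2, and 8 were lower at an unadjusted p under 0.05. In the edgeR fit with 1 surrogate variable Cd28 and Prf1 passed as falls (adjusted p = 0.03 and 0.037). Gzma, a granule protease gene of cytotoxic cells, had the smallest adjusted p of that list (0.0631). By fry the list had an adjusted p of 0.15, and 2 other splits of the libraries gave it a lower camera p. By edgeR 2 T and NK genes fell without control replicate 1, where Gzma was at an adjusted p of 0.029 and Prf1 at 0.044, 2 without TGFalpha replicate 2 and 1 without TGFalpha replicate 3. Antigen presentation and dendritic cell genes gave 3 falls and 1 rise of 25 (5 and 1 adjusted over the list alone). With 1 library left out 0 to 3 fell, with 1 without control replicate 1 and none by edgeR without control replicate 2, control replicate 3 or TGFalpha replicate 1, where 7, 5 and 5 were lower at an unadjusted p under 0.05. Clec9a, a dendritic cell receptor gene, fell from 53.1 ± 16.6 to 16.7 ± 5.93 CPM and Ccl22 from 18.9 ± 3.56 to 5.69 ± 3.6 CPM, while Fscn1 rose from 23.8 ± 6.29 to 62.6 ± 20.3 CPM. For antigen presentation camera gave an adjusted p of 0.04 and the adjusted p = 0.77 with an estimated correlation. That call was lost without control replicate 1, TGFalpha replicate 1 or TGFalpha replicate 3 (adjusted p = 0.16, 0.18 and 0.13), and with control replicate 1 and TGFalpha replicate 1 both left out (0.42). The calls of Clec9a, Ccl22 and Fscn1 were each lost without control replicate 2, control replicate 3 or TGFalpha replicate 1 (adjusted p between 0.063 and 0.14), those of Clec9a and Fscn1 also without TGFalpha replicate 2 (0.066 and 0.078), and that of Ccl22 also without control replicate 1 or TGFalpha replicate 3 (0.069 and 0.099). In the interferon response list only Rsad2 of 32 genes fell by the main edgeR fit (log2 fold change -1.41 ± 0.34), and it missed the threshold when adjusted over the list alone. Rsad2 also missed it without control replicate 2, control replicate 3, TGFalpha replicate 1 or TGFalpha replicate 3 (adjusted p = 0.15, 0.14, 0.14 and 0.1). DESeq2 called 3 of these genes down, among them Ifih1 (0.031), which also passed in the edgeR fit with 1 surrogate variable (0.046). By edgeR 2 interferon genes fell without TGFalpha replicate 2, and 1 rose without TGFalpha replicate 3. Interferon genes had a camera adjusted p of 0.011 and the adjusted p = 0.77 with an estimated correlation, and the call was lost without control replicate 3, TGFalpha replicate 1 or TGFalpha replicate 3 (0.053, 0.18 and 0.088), and with control replicate 1 and TGFalpha replicate 1 both left out (0.21).

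Of the other immune lists none shifted by camera. In the list of type 2 immunity and alternative activation 2 of 26 genes rose and 4 fell (5 and 4 adjusted over the list alone), with a median of -0.02, a mean of 0.04 and a camera adjusted p of 0.79 in the downward direction. The falls in this list numbered 1 without control replicate 1, TGFalpha replicate 2 or TGFalpha replicate 3, and none by edgeR without control replicate 2, control replicate 3 or TGFalpha replicate 1, where 4, 6 and 4 were lower at an unadjusted p under 0.05. Its rises numbered 1 without control replicate 3 and none by edgeR without control replicate 2, where 4 were higher at an unadjusted p under 0.05. Arg1, the arginase gene, rose from 3.56 ± 1.83 to 87.4 ± 65.6 CPM, and its call was lost without control replicate 2 or control replicate 3 (adjusted p = 0.064 and 0.065). The neutrophil list had 2 rises and 1 fall among 22 genes, the fall being Cxcl5 (23.6 ± 11.1 to 4.91 ± 2.59 CPM). Rises in the neutrophil list numbered 1 without control replicate 1 and none by edgeR without control replicate 2, control replicate 3, TGFalpha replicate 1 or TGFalpha replicate 2, where 2, 4, 3 and 3 were higher at an unadjusted p under 0.05, and 2 fell without TGFalpha replicate 2. The neutrophil counts were the same when adjusted over the list alone. The Cxcl5 call was lost without control replicate 2, TGFalpha replicate 1 or TGFalpha replicate 3 (adjusted p = 0.077, 0.09 and 0.059). The median of the neutrophil list was -0.32, its mean was 0.03 and camera placed it down (adjusted p = 0.53). In the mast cell list 2 of 10 genes rose and 2 fell (2 and 2 adjusted over the list alone), with a camera adjusted p of 0.79. The falls were Gata2 and Kit, the latter from 179 ± 37.1 to 58.7 ± 22.9 CPM. The rises were Mcpt2 and Tpsab1, with log2 fold changes of 8.4 ± 1.4 and 4.02 ± 1.02. They passed in 2 and 1 of the 6 edgeR fits with 1 library left out. Mast cell rises numbered 1 without TGFalpha replicate 3 and none by edgeR without control replicate 2, control replicate 3, TGFalpha replicate 1 or TGFalpha replicate 2, where 2 were higher at an unadjusted p under 0.05 in each. Its falls numbered 1 without TGFalpha replicate 1 and none by edgeR without control replicate 2, control replicate 3 or TGFalpha replicate 2, where 2 were lower at an unadjusted p under 0.05 in each. The Kit call was lost without control replicate 2, control replicate 3 or TGFalpha replicate 2 (adjusted p = 0.07, 0.089 and 0.063). The B cell chemoattractant gene Cxcl13 rose from 24.5 ± 13.1 to 145 ± 47.3 CPM and was the called gene of 22 in the B cell list, which had a camera adjusted p of 0.16. It was also the called gene when adjusted over the list alone. The Cxcl13 call was lost without control replicate 2 or control replicate 3 (adjusted p = 0.059 and 0.062), and the B cell list was called down without TGFalpha replicate 2 (0.0026). Among 12 nerve and neuroendocrine genes 3 rose (4 adjusted over the list alone; camera adjusted p = 0.14, or 0.026 with the stricter filter), including Calca, which encodes calcitonin and calcitonin gene-related peptide (1.62 ± 0.761 to 57.6 ± 15.9 CPM).

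Transcripts of other tissues and of sample handling were measured alongside. Red blood cell genes fell in 6 of 10 cases, or 8 adjusted over the list alone (median log2 fold change -1.48, camera adjusted p = 5e-05; adjusted p = 0.71 with an estimated correlation), and all 6 were globin genes whose near-identical copies share reads. Globin genes took 2.72, 6.04 and 4.75% of the counts in controls and 2.02, 1.09 and 1.63% in CCSP/TGFalpha libraries. Without any 1 library other than control replicate 1, no red blood cell gene passed with edgeR, while 8 were lower at an unadjusted p under 0.05. By fry the red blood cell list had an adjusted p of 0.12. In 1 other split of the libraries its unadjusted camera p was lower (1.4e-12 against 1.1e-05). In the heart and vein muscle list Actc1 was the called gene of 18 and fell from 47.2 ± 13.5 to 16.2 ± 6.62 CPM, with 2 falls adjusted over the list alone. Its call was lost without any 1 library other than TGFalpha replicate 3 (adjusted p between 0.06 and 0.13), and 2 genes of the list fell without TGFalpha replicate 3. By camera the heart and vein list had an adjusted p of 0.047 and the adjusted p = 0.77 with an estimated correlation. It was lost without control replicate 1, control replicate 3, TGFalpha replicate 2 or TGFalpha replicate 3 (0.27, 0.1, 0.21 and 0.39) and with the size factors of DESeq2 (0.052), and the list median went to 0.15 without control replicate 1. The heart and vein genes were also highest in the libraries with high skeletal muscle transcripts, with mean log2 levels relative to the control mean of 1.05 in control replicate 1 and 0.80 in TGFalpha replicate 1, against -1.66 to -0.03 in the other libraries. Skeletal muscle genes did not follow the groups. The CPM of the 14 tested genes summed to 1977, 72 and 87.9 in control replicates 1 to 3 and to 3205, 84.9 and 83.8 in TGFalpha replicates 1 to 3. None passed with the main edgeR fit, DESeq2 or limma-voom, or at an unadjusted p under 0.05, and Actn3 had the smallest adjusted p (0.644). The skeletal muscle list had a camera adjusted p of 0.84, and it was called up without control replicate 1 (0.043). No adipocyte gene of 12 passed with any of these tools or at an unadjusted p under 0.05 (camera adjusted p = 0.79). Of 19 genes that respond to ischaemia and dissection 5 fell and 1 rose (6 and 2 adjusted over the list alone), with Klf2 falling from 101.6 ± 13.2 to 37.7 ± 3.85 CPM, and the list was not called (adjusted p = 0.24) except without control replicate 3 (0.029). The falls among them numbered 1 without control replicate 2, 2 without TGFalpha replicate 2, and 3 without control replicate 3, TGFalpha replicate 1 or TGFalpha replicate 3. The rise was kept by edgeR only without control replicate 1, while 2, 1, 2, 3 and 3 were higher at an unadjusted p under 0.05 in the others.

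The genes with the largest changes included several with no or almost no control counts. Krt76, Defb48, Ano4, Gbx2 and Rxfp3 had 0 counts in all 3 control libraries. Against a floor of 3 counts over the control group they were at least 140-fold, 153-fold, 121-fold, 99.8-fold and 46.9-fold higher in CCSP/TGFalpha lungs, limits that cover counting error only. Rxfp3 (chromosome 15, 11033717 to 11037968) lies close to Adamts12 (11064773 to 11349232), which also rose. The transcription factor gene Twist1 had 2 control counts and 1424 in CCSP/TGFalpha libraries, a ratio of 681 with a 95% counting interval of 188 to 5630. Angptl7 (gene ID 654812; chromosome 4, 148495181 to 148500462) rose from 0.514 ± 0.327 to 277 ± 10.6 CPM (log2 fold change 9.07 ± 0.39, edgeR adjusted p = 0.00011) and Gdf6, a BMP family growth factor gene, from 0.264 ± 0.283 to 42 ± 19.1 CPM. Among falling genes with a mean of at least 1 CPM and no overlap between the groups, Coch (-3.81 ± 0.49), the endothelial adhesion gene Sele (-3.05 ± 0.36), Entpd8 (-2.85 ± 0.37) and the estrogen receptor gene Esr2 (-2.65 ± 0.41) had the largest log2 fold changes. They were followed by Prrt4 (-2.48 ± 0.55), Atp2b2 (-2.41 ± 0.47), Slc5a12 (-2.40 ± 0.38) and Ptgs2os2 (-2.38 ± 0.42). The calls of Esr2 and Slc5a12 were lost without control replicate 2 or control replicate 3 (adjusted p between 0.054 and 0.06). Those of Prrt4, Atp2b2 and Ptgs2os2 were lost without these and also without TGFalpha replicate 1 or TGFalpha replicate 2 (0.051 to 0.15). Reads of the antisense RNA gene Ptgs2os2 could not be told from those of a gene on the other strand, since the strand setting of the counts was not given in the sources used here.

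List calls by camera were not rare in other groupings of these libraries. Of 38 lists, 20 were called, 10 up and 10 down, with a preset correlation, and none with an estimated correlation, where the lowest unadjusted p was 0.016 and the lowest adjusted p was 0.6. With an estimated correlation camera also rests on the few residual degrees of freedom of 6 libraries, which leaves little power. Even the matrix list had an unadjusted camera p of 0.035 in that setting. The lack of calls therefore does not show that no list shifted. By fry 4 lists passed, namely matrix, cross-linking, proteases and inhibitors, and ciliated cell. The other lists called by camera had a fry adjusted p between 0.068 and 0.46. In the 10 ways of parting the 6 libraries 3 against 3, the true grouping gave 20 called lists and the others gave 12 to 21. The matrix, cross-linking, protease, ciliated, cell cycle and ribosomal lists had their lowest camera p in the true grouping. The lead was widest for matrix and small for the protease and cell cycle lists, and for the ribosomal list another split was almost level. These lists were also called in other splits, namely 7 for ciliated and ribosomal, 6 for matrix and cell cycle, and 2 for cross-linking and protease. The rank alone therefore does not tie the ribosomal, protease or cell cycle shift to genotype. Of the other splits, 1 gave a camera p as low for the ERK, endothelial, alveolar type 1, lipid and red blood cell lists. For TGF-beta, T and NK, and glycolysis 2 did, and for oxidative phosphorylation 6. For the club cell, antigen presentation, interferon, unfolded protein, and heart and vein lists 4 did. The counts of single genes differed more, with 1340 in the true grouping and 0 in the others by edgeR, where 129 to 1612 genes had an unadjusted p under 0.05. Each other split holds libraries of both genotypes in both arms. A difference between genotypes would widen the spread within these arms, so the 0 is not a chance level.

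The libraries differed within groups as well as between them. The first principal component of the 500 most variable genes held 47.8% of the variance and placed TGFalpha replicate 1 at 50.54 and control replicate 1 at 9.44, with control replicates 2 and 3 at -38.69 and -34.12. The second held 35.7% and placed TGFalpha replicates 2 and 3 at 30.46 and 32.87 and control replicate 1 at -43.87. Correlations of log2 CPM ran from 0.9476 to 0.9721 within groups and from 0.8971 to 0.9502 between groups. With control replicate 1 and TGFalpha replicate 1 left out, the libraries with high skeletal muscle transcripts, 473 genes changed, 307 up and 166 down, and 445 of them were among the 1340.

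**Figure D4:**
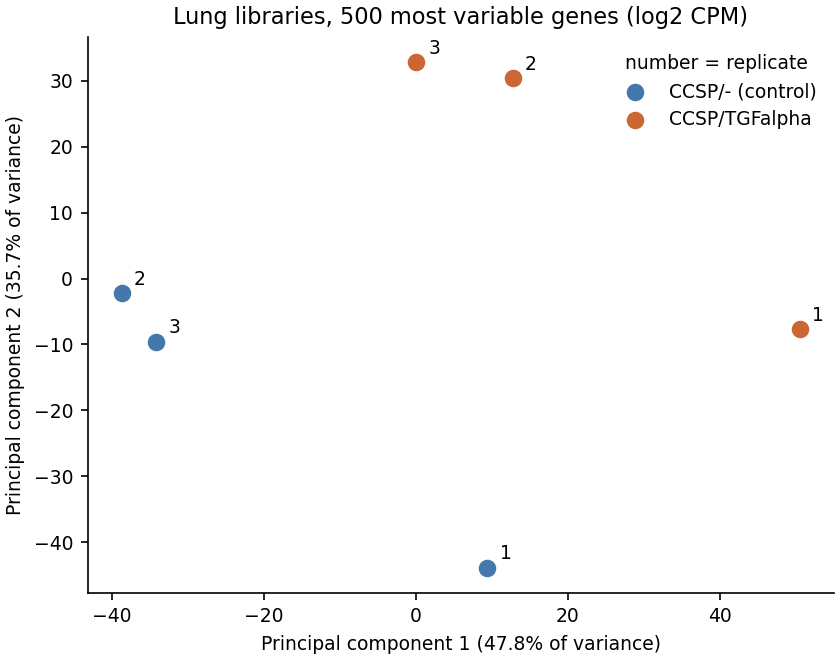
The 6 libraries on the first and second principal components of log2 CPM over the 500 most variable genes, with 47.8% and 35.7% of the variance on the x and y axes and the replicate number beside each point. Replicates 2 and 3 of each group lie together, and replicate 1 of each group lies apart from them.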

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

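The alternatives added after the results were seen are marked as such. The replicate numbers did not clearly pair the samples, with correlations of deviations of 0.42, -0.05 and 0.22 for replicates 1 to 3. Control replicate 2 and TGFalpha replicate 3, which differ in number, were at 0.38. These few values cannot exclude pairing. The replicate block gave 1470 changed genes, 802 up and 668 down, with 1143 shared with the unblocked fit, and 16 called lists. With the block the TGF-beta (adjusted p = 0.067), club cell (0.054), antigen presentation (0.054) and unfolded protein response (0.059) lists no longer passed. Of the named genes, Sqle (edgeR adjusted p = 0.053), Insig1 (0.053) and Hbb-bs (0.06) no longer passed with it. Those that passed only then included Notch3 (0.014), Manf (0.016), Tnni3 (0.032), Actn3 (0.036), Ndufb5 (0.037) and Cd28 (0.039), against the unblocked main fit. Scaling, filtering, limma-voom, the robust fit and removal of the 20 most abundant genes gave 1266 to 1481 changed genes. DESeq2 gave 2506 changed genes, 1281 up and 1225 down, among them all 1340; it tested more genes, and made more false calls in the simulation. With 1 surrogate variable, added after seeing the data, 938 genes fell. An adjusted p of 0.01 left 260 genes, 227 up and 33 down, with 259 at least 2-fold, and the test against a 1.5-fold change left 294, 254 up and 40 down, by construction stricter.

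Leaving out 1 library gave 238 to 1088 changed genes, 204 to 606 up, 34 to 482 down and 236 to 935 at least 2-fold. By library the changed genes were 1002 without control replicate 1 (529 up), 307 without control replicate 2, 238 without control replicate 3, 411 without TGFalpha replicate 1, 564 without TGFalpha replicate 2 and 1088 without TGFalpha replicate 3. Leaving out control replicate 1 and TGFalpha replicate 1, chosen after seeing the data, gave 473 changed genes, 307 up and 166 down, with 444 at least 2-fold. These fits have fewer samples, and which part of the loss follows from that was not tested. Lists called ranged from 15 to 19 when 1 library was left out, 0 with an estimated correlation and 4 by fry. Tgfa stayed between 0.007 and 0.162 (log2) and uncalled in every setting.

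Of 79 called named genes, 79 kept their direction in every setting in which they were tested and 30 stayed past the threshold in every one. Actn3, which was not called in the main fit, reversed to -2.427 without TGFalpha replicate 1, a library with high muscle transcripts. It ranged up to 7.88 without control replicate 1, the other such library, and the cause was not tested. With the replicate block Actn3 was called up (log2 fold change 2.15, edgeR adjusted p = 0.036). Depth limits the genes with 0 control counts to lower bounds, and the simulated recovery of 2-fold changes was 16%.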

Other observations

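The tests of Tgfa, of dilution, of fibroblast number and of the skeletal muscle list were chosen after the results were seen; the further muscle genes were listed after the muscle pattern was seen but before their own values were. The genes of the next 2 paragraphs were chosen after their values were seen.

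The 8 genes given here belong to none of the lists and were not tested as a group. Ptn, which encodes pleiotrophin, rose from 1.57 ± 0.765 to 54.9 ± 8.51 CPM (mean ± SD, n = 3), its relative Mdk from 5.11 ± 1.34 to 70.8 ± 24.6 CPM, Fgf2 from 1.96 ± 0.586 to 16.7 ± 2.12 CPM and Pdgfc from 3.36 ± 0.446 to 21 ± 3.72 CPM. The Wnt receptor gene Fzd1 rose from 43.6 ± 1.9 to 219 ± 26.9 CPM, Ror2 from 0.7995 ± 0.0377 to 7.71 ± 1.34 CPM and the Wnt-induced gene Ccn4 from 8.39 ± 2.55 to 82.7 ± 27.8 CPM. Wif1, a secreted Wnt inhibitor, fell from 23.4 ± 5.52 to 5.23 ± 1.33 CPM. Each of these 8 genes passed in all 6 edgeR fits with 1 library left out, with Wif1 having the highest adjusted p (0.034).

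Within the macrophage list, the complement gene C1qa rose from 30.8 ± 8.23 to 128.6 ± 39.6 CPM and Apoe from 56.5 ± 10.1 to 241.5 ± 68 CPM, and both passed in all 6 fits with 1 library left out, where the highest adjusted p was 0.049 for C1qa. Its sister genes were less stable: C1qb rose from 27.2 ± 11.2 to 103.3 ± 36.8 CPM and passed in 2 of the 6 fits (highest adjusted p 0.11), and C1qc rose from 27.7 ± 9.77 to 108 ± 30.6 CPM and passed in 4. Folr2 rose from 1.6 ± 0.354 to 7.51 ± 2.16 CPM and passed in 4 of the 6.

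Chance was tested with the 10 splits of the 6 libraries into 3 and 3, too few for a share under 0.05. The other splits also mix both genotypes in each arm, which widens the spread there if the genotypes differ. Their gene counts therefore cannot serve as a chance level. For changed genes 1 split, the true one, gave 1340, and the highest other gave 0. The same held for rises (1 split; 810 against 0), falls (1 split; 530 against 0) and changes of at least 2-fold (1 split; 917 against 0), while the others had 129 to 1612 genes at an unadjusted p under 0.05. For called lists 2 splits gave as many as the true one (20 against a highest other of 21), namely the true one and the split of control replicate 1 with TGFalpha replicates 1 and 2.

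The Tgfa transcript was not raised in CCSP/TGFalpha libraries. Exchanged group labels would place the ERK feedback list lower in the CCSP/TGFalpha libraries. Its mean log2 level was higher by 0.43 in the lowest CCSP/TGFalpha library than in the highest control, beyond the widest range within a group (0.27). The mean log2 fold change of that list was 0.65 and its median 0.22, so a part of its genes carried the gap. The rise of the list had been seen before this test was chosen, and the test takes the direction of ERK feedback under TGFalpha as known. It therefore cannot decide on the labels. Another explanation that stays open is that transgene reads were not counted at the mouse gene. The row's log2 fold change of 0.09 (-0.21 to 0.4) fits that reading as well as a weak transgene, and only the reads could decide it.

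The falls of endothelial, alveolar type 1 and ciliated transcripts may reflect fewer of these cells or lower output per cell, which bulk RNA cannot separate. The endothelial median lay below the alveolar type 2 median (-1.19, 95% bootstrap interval over genes -1.33 to -0.75), which an equal dilution of all resident cells would not give. That interval leaves out the spread between samples. In control replicate 1 the endothelial and alveolar type 2 lists had mean log2 levels relative to the control mean of -0.4 and 0.36. In TGFalpha replicate 3 these were -0.65 and -0.05. The test therefore cannot decide on dilution. A trend with transcript length and GC content is argued against, because after it was removed the smallest of the 3 list medians was still -0.8. The difference between genotypes stays open as a biological hypothesis.

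Skeletal muscle transcripts were high in control replicate 1 and TGFalpha replicate 1, and 14 of 14 tested list members were higher in both than in the other 4 libraries. That list is where the pattern was seen, so this count cannot decide its source; its most abundant member, Acta1, was at 489.5 and 742 CPM in these and at 48.4 to 62.2 CPM in the others. Of 23 further muscle genes, 22 were higher in both, against 5.7% of all tested genes, which is consistent with muscle tissue carried along with the lung in these samples. The pattern does not follow the groups, and no biological explanation was tested.

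A further hypothesis is that matrix transcripts rose only through more fibroblasts of the same output. The median log2 fold change of the matrix list exceeded that of the fibroblast list by 1.63 (95% bootstrap interval over genes 0.67 to 2.43). This argues against it as far as those markers count fibroblasts, and the interval leaves out the spread between samples.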
